A study of Homo sapiens with 2 samples.

How the data were processed

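Messenger RNA was sequenced from 2 tumours grown from the DOHH2 cell line in SCID mice, which lack functional B and T lymphocytes. One library came from the parental tumour and 1 from the rituximab-resistant tumour, and samples were grouped by these titles. Per the labels' protocols, RNA was selected with oligo(dT) beads and sequenced with standard Illumina library preparation. The label of each library states that the RNA included sequences from the mouse host.

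The authors deposited 1 value per gene, the log2 of RPKM (reads per kilobase of gene, scaled to the mapped reads of the library), for 23027 human genes with their positions, per the file headers. TopHat2 2.0.4, HTSeq 0.5.3p9 and the builds hg19 and mm10 are named in the submitters' processing notes. The gene annotation, the use of strand, the way mouse reads were set apart and the reads counted in the denominator are not given in the sources used here. The deposited log2 values are logs of RPKM rounded to 3 decimals with no constant added, and a gene whose RPKM rounds to 0 is blank. Blanks (5370 genes in the parental library and 5828 in the resistant library, 4748 of them in both) were read as 0 RPKM. A blank is not always low expression: TUBB and RPS18, which every cell uses and which were picked after the values were seen, are blank in both libraries, as are many genes of the HLA region. Such genes fall below the filter and are not measured here. Positions are on hg19 and are given 1-based.

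The read depth was estimated from the step between low RPKM values of single-exon genes, where 1 read has a known worth. A depth of 103900000 reads for the parental library made 91.4% of 35 genes whole within 0.1 read, and 88900000 for the resistant library made 100% of 36 genes whole, against 20% by chance. Each depth was itself chosen to make these genes whole, so the shares are not an independent check, and no count test was run on reads rebuilt in this way. At these depths, 1 RPKM on a 1 kb gene stands for 104 and 89 reads. The 95% interval of a difference from counting error alone then reaches to either side by 0.20 on the log2(RPKM + 1) scale at 1 RPKM, 0.15 at 5 RPKM, 0.087 at 20 RPKM and 0.040 at 100 RPKM for such a gene. It leaves out all variation between tumours.

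Each value was returned to RPKM, 1 RPKM was added, and the difference of log2(RPKM + 1), resistant minus parental, was taken. This scale understates the change of low genes. Genes at 1 RPKM or more in at least 1 library were counted as 2-fold higher or lower where the difference was at least 1 in size. With 1 library per group there was no replicate check, no p-value was computed, and this rule of size compares the libraries, not the conditions.

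Before the data were examined, 41 gene lists were fixed. They covered B-cell identity and signalling, the BCL2 family and cell death, antigen presentation, complement regulators, interferon and NF-kB responses, growth and metabolism, adhesion, markers of other cell types and RNA quality. The median difference of a list with at least 5 members at the filter was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart where its percentile was under 2.5 or over 97.5, which describes these 2 libraries only. Of 31 lists placed, 1.6 would stand apart by chance if the members of a list were no more alike than random genes. Genes of a list can vary together, and several lists share members, so this number is not a fair baseline for the count. The genes named were also fixed by rule: MS4A1, all BCL2 family members, a set of other B-cell antigens that includes CD22, CD37, CD79A and CD79B, the 12 highest and 12 lowest differences at 5 RPKM or more, and the 4 members of each list with the differences of largest size. Clone, pseudogene, immunoglobulin segment, T-cell receptor segment and sex-linked marker names were kept out of the ranked genes. Not every gene that the rule allows is named, and some are not reported here.

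The steps were tested on simulated data. For a simulated resistant against parental comparison of 11364 genes with assumed lengths of 1 kb, 49 of 50 genes changed 2.5-fold, 50 of 50 changed 4-fold and 47 of 50 lowered to 0.25 of their level met the 2-fold rule. None of 50 genes changed 1.5-fold and 0 of 11164 unchanged genes met it. These libraries were simulated with counting error only and no variation between tumours. They therefore say nothing about calls that such variation would make. On the real differences, 10 of the 100 lists of 30 random genes first drawn stood apart, more than the 5% the rule allows. The draw was therefore extended to 500 lists, of which 31 (6.20%) stood apart, and 491 (98.2%) did so after a shift of 0.4 was added to their members.

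Alternatives fixed in advance changed the pseudocount, the filter, the scaling of the libraries, the threshold, or left out members of the lists of other cell types. Removal of a trend with GC content and removal of genes on haplotype and unplaced sequences were added after the data were seen. Transcript GC came from a GRCh38 annotation matched by gene symbol, with a value for 95.9% of the genes at the filter, and no position was taken from that build. Mitochondrially encoded genes and mouse genes were not analysed here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.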

Results

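Rituximab is an antibody against CD20, a surface protein of B cells, and is the antibody part of R-CHOP. DOHH2 is a human line of diffuse large B-cell lymphoma of the germinal-centre B-cell like subtype, and it carries the translocation that places BCL2 under control of the immunoglobulin heavy chain locus. The series title concerns a BCL2 inhibitor in CD20-negative lymphoma. The data compare gene expression between a parental DOHH2 xenograft and a rituximab-resistant one, with 1 library each. The protocol in the labels describes rituximab at 25 mg/kg into the peritoneum 3 times a week over 21 days, started on day 10 to 12 in tumours of 200 to 250 mm3. This text stands with both libraries, and how the resistant tumour was derived is not given in the sources used here. The parental library was estimated at 103900000 mapped reads and the resistant library at 88900000. At 1 RPKM or more, 11190 genes were measured in the parental and 11101 in the resistant library. Where a pair of RPKM values is given, the parental library comes first, and differences are resistant minus parental on the log2(RPKM + 1) scale. The statement that a gene was 2-fold different or within 2-fold is also on that scale, which for low genes gives smaller folds than the RPKM ratio.

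The first question was whether the resistant tumour carried less CD20 transcript. MS4A1, the gene of CD20 (chromosome 11, 60223282 to 60238225, hg19), was at 170 RPKM in the parental library and 19.5 RPKM in the resistant library. The RPKM was 8.68-fold lower, or 11.5% of the parental level, and the difference on the log2(RPKM + 1) scale was -3.05. MS4A1 transcript was still measured in the resistant library, where it ranked 3578th by RPKM, compared with 382nd in the parental library. Of its gene family, 4 members were measured, and all 4 were lower. MS4A6A was at 48.8 and 0.305 RPKM and MS4A7 at 4.32 and 1.56 RPKM, while MS4A4A (3.73 and 1.47 RPKM) differed by -0.94. CD20 protein was not measured in these data.

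The other B-cell antigens reported here did not share the low level of MS4A1. CD22 (88.2 and 73.0 RPKM) and CD79A (709 and 620 RPKM) differed by -0.27 and -0.19. CD79B, the partner of CD79A in the B-cell receptor, was higher in the resistant library (119 and 298 RPKM, a difference of 1.32). CD37 was at 429 RPKM in the parental and 579 RPKM in the resistant library. It overlaps TEAD2, and reads of the pair cannot be told apart without strand.

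Across the transcriptome, 395 genes (3.38% of 11671) were at least 2-fold higher and 693 (5.94%) at least 2-fold lower in the resistant library. These counts depend on the pseudocount, with 93 higher and 272 lower at 5 RPKM and 684 higher and 978 lower at 0.1 RPKM. At 8-fold, 7 were higher and 49 lower. The median difference of all genes was -0.01, with quartiles of -0.33 and 0.28, and the correlation across genes was 0.94, over genes that are not independent replicates. Differences ran weakly with transcript GC content, with a Spearman correlation of -0.25 across genes. The lowest genes were CCL22 (124 and 0.104 RPKM) and CCL17 (179 and 0.749 RPKM), chemokines that attract T cells. CD48, a surface protein of lymphocytes at 159 RPKM in the parental library, differed by -6.32. Its relative SLAMF7 was at 27.8 and 0.047 RPKM. CD44, an adhesion receptor for hyaluronan, was at 26.9 and 0.233 RPKM. SRGN (-5.09), PARVB (-5.06) and EBI3 (-4.53), a cytokine subunit, were also among the 12 lowest. CCL3 (-5.27) has near-identical copies with which it can share reads.

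**Figure D1:**
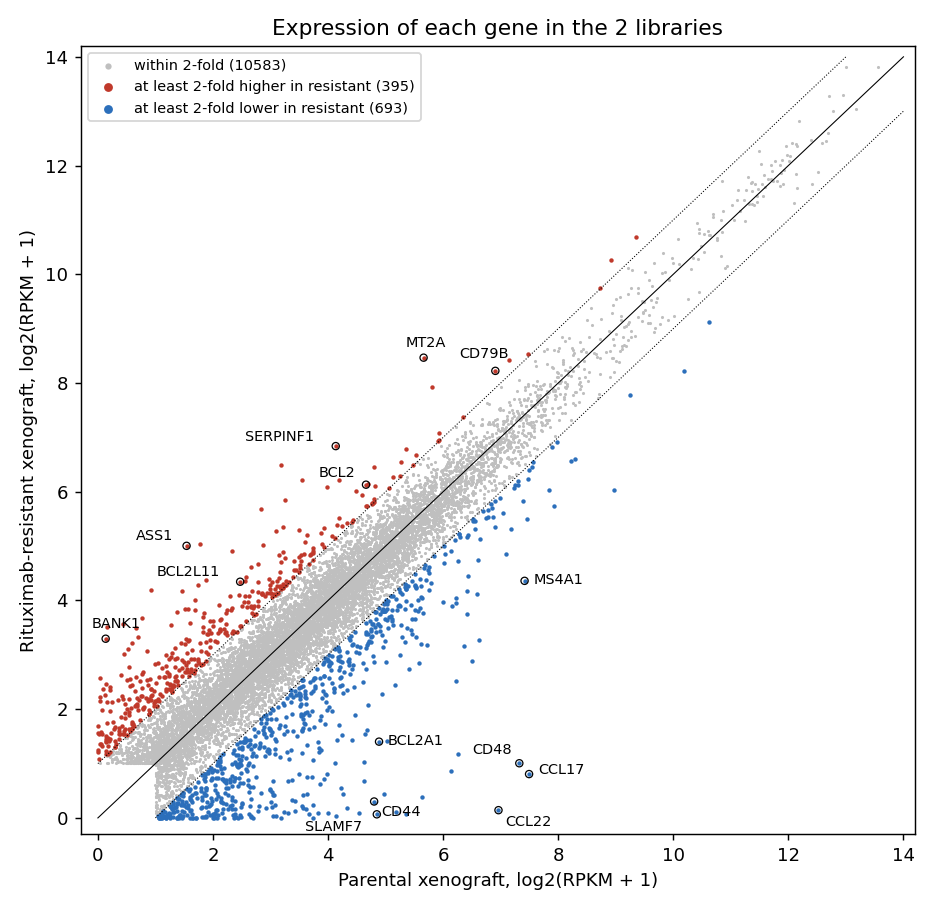
Expression of each of 11671 genes as log2(RPKM + 1), with the parental library on the horizontal axis and the resistant library on the vertical axis. Each point is 1 gene, dotted lines mark a 2-fold difference, and MS4A1 (-3.05) lies below the lower line.

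Genes at the other end included ASS1, an enzyme of arginine synthesis, at 1.91 RPKM in the parental and 31.1 RPKM in the resistant library. The inhibitory receptor LAIR1 was at 2.42 and 31.7 RPKM, and BANK1, a B-cell scaffold protein, at 0.098 and 8.83 RPKM. VPREB1, part of the surrogate light chain of early B cells, was at 0.585 and 10.2 RPKM. SERPINF1 was at 16.6 and 114 RPKM. The metallothioneins MT2A (49.6 and 353 RPKM) and MT1F (8.04 and 89.3 RPKM) and the histone gene HIST1H4C (6.13 and 50.6 RPKM) were also higher. These last 3 belong to families of similar sequence, so their reads can be split between copies. HIST1H4C belongs to a list fixed as a measure of RNA quality, of which 3 of 13 members were higher and 1 lower. Its value cannot tell a difference in expression from one in the selection of RNA with oligo(dT) beads.

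The next question was the BCL2 family, since the study's drug targets BCL2. BCL2 (chromosome 18, 60790579 to 60986613, hg19), which blocks apoptosis, was 2.84-fold higher in the resistant library, at 24.3 and 69.0 RPKM. The other anti-apoptotic genes at the filter were all lower, but MCL1 (-0.56) and BCL2L2 (-0.28) stayed within 2-fold. BCL2A1 was at 28.6 and 1.65 RPKM, BCL2L1, the gene of BCL-XL, at 21.4 and 7.28 RPKM and MCL1 at 39.5 and 26.4 RPKM. BCL2L2, which overlaps BCL2L2-PABPN1, was at 5.98 and 4.75 RPKM, and BCL2L10 was below the filter. The list of 5 measured anti-apoptotic genes had a median of -0.56, at percentile 1.11 of the random lists, with BCL2 as its 1 positive member.

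The pro-apoptotic members went both ways. BCL2L11, the gene of BIM, was 4.25-fold higher in the resistant library (4.55 and 19.3 RPKM), and HRK was 3.08-fold higher (a difference of 1.46). BAD, which overlaps GPR137, was 2.37-fold lower (27.7 and 11.7 RPKM). PMAIP1, the gene of NOXA, differed by -0.98, BMF by -0.69, BID by -0.63 and BBC3, the gene of PUMA, by -0.24. BIK differed by 0.89 on the log2(RPKM + 1) scale, although its RPKM was 2.51-fold higher (1.29 and 3.24 RPKM), BNIP3L by 0.58 and BNIP3 by 0.44. The 10 BH3-only genes together had a median of 0.10, within the range of random lists. The effectors BAX (86.2 and 84.1 RPKM) and BAK1 (18.4 and 14.6 RPKM) stayed within 2-fold, as did BCL2L13 (-0.01). The 4 measured multidomain genes had a median of -0.18. BCL2L14 (1.09 and 0.018 RPKM) was near the filter and BOK was below it.

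**Figure D2:**
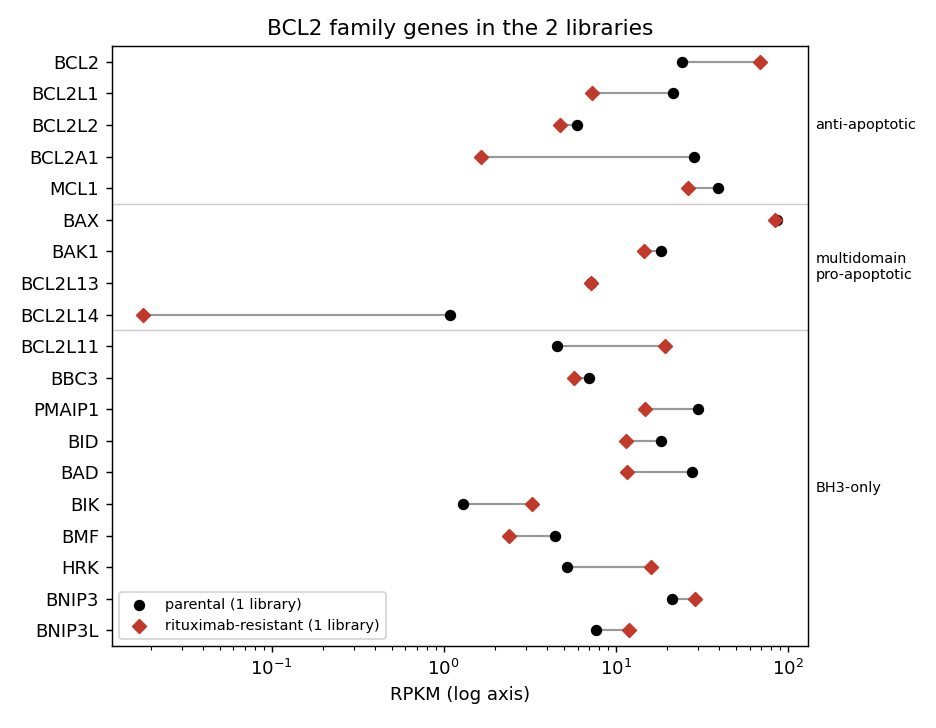
RPKM of the BCL2 family genes at the filter, on a log axis, in the parental library (circles) and the resistant library (diamonds). BCL2 is higher in the resistant library (24.3 and 69.0 RPKM), BCL2A1 and BCL2L1 are lower, and the BH3-only genes lie on both sides.

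The question of which other programmes differed was addressed with the fixed lists, of which 17 of 31 stood apart from random lists, 11 lower and 6 higher. Of the lists placed, that of NF-kB target genes was the lowest at the pseudocount and filter used throughout. All 25 measured members were negative, 16 were at least 2-fold lower and 0 higher, and the median was -2.05 (percentile 0.00). That median depends on the settings, and was -1.35 with a pseudocount of 5 RPKM and -0.82 without a filter, with percentiles that kept the list apart. Its rank depends on them too. The fibroblast and matrix list was lower with no pseudocount (-2.48 against -2.23), and the interferon list was lower without a filter (-1.34 against -0.82). Beside CCL22, EBI3 and CD44, the NF-kB list includes BCL2A1. Interferon-response genes came next among the large lists, with 27 of 41 members at least 2-fold lower, 0 higher and a median of -1.52 (percentile 0.00), or -0.77 with a pseudocount of 5 RPKM. Antiviral genes IFI44L (23.6 and 0.605 RPKM), IFI6 (73.4 and 4.76 RPKM) and IFIT3 (31.7 and 1.67 RPKM) were examples. Immediate-early genes, many of which respond to stress during tissue handling as well as to signals, had a median of -0.77 over 15 members (percentile 0.00). Of these, 4 were at least 2-fold lower, including JUN (4.76 and 0.558 RPKM) and JUNB (44.6 and 11.6 RPKM). Fibroblast and matrix markers (median -1.46) were lower beside these lists too.

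Genes of activated B cells and plasma cells were lower, with 15 of 32 members at least 2-fold lower, 1 higher and a median of -0.81 (percentile 0.00). BATF was at 14.9 and 0.753 RPKM, and CCND2, a cyclin, differed by -3.12. B-cell surface and co-receptor genes had 17 of 42 members lower, 2 higher and a median of -0.76 (percentile 0.00). The homing receptor CCR7 was at 19.0 and 0.134 RPKM and IL4R at 11.5 and 0.354 RPKM. Adhesion and migration genes had 15 of 31 members lower, 1 higher and a median of -0.94 (percentile 0.00), with LGALS1 at 500 and 64.5 RPKM. These lists share members such as CD44 and CCR7, so their counts overlap. The fibroblast and matrix markers described next were lower beside them.

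Markers of fibroblasts and extracellular matrix, which could come from host tissue or from the tumour cells, also stood apart on the lower side. Of 6 measured members 3 were at least 2-fold lower, with a median of -1.46 (percentile 0.01; -0.63 with a pseudocount of 5 RPKM). Without a filter the list had a median of -0.0021 and did not stand apart (percentile 16.5). TIMP1 (11.4 and 0.675 RPKM) and SERPINH1 (8.83 and 0.603 RPKM) were the farthest. Markers of macrophages, monocytes and neutrophils had a median of -0.34 over 6 members, within the range of random lists, with LYZ (7.92 and 22.1 RPKM) higher and ITGAX lower (2.32 and 0.288 RPKM). LYZ lies on chromosome 12 in a segment of 263 genes with a median of 0.45. With a filter of 5 RPKM the median of the list was 0.48. T-cell and NK-cell markers (7 members) had a median of -0.24, also within the range. Fewer than 5 members were measured for endothelial cells (4, median 0.09), skeletal muscle (3, median 0.40), epidermis (3, median -0.77), adipocytes (2, median 0.48) and erythroid cells (1, HBA1, -0.88).

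Genes of MHC class II presentation had a median of -0.56 over 9 members (percentile 0.16), of which 1 was at least 2-fold lower, HLA-DQA1 (95.0 and 16.3 RPKM). Genes of MHC class I presentation had a median of -0.38 over 10 members (percentile 2.11), none of them 2-fold different. Without a filter, where blanks enter as 0, both lists had medians of 0.00 and did not stand apart (percentile 50.1 for class II and 51.4 for class I). With a pseudocount of 5 RPKM the class I list was at percentile 3.15, and without haplotype and unplaced sequences at 3.67, so its call did not hold throughout. B2M, the light chain of class I, was at 1394 RPKM in the parental and 819 RPKM in the resistant library. Of the 19 class II genes in the files 9 were blank in both libraries, among them HLA-DRA, and of the 20 class I genes 8 were, so these lists describe only the members with a value. Such a blank need not mean absence, since TUBB, a gene that every cell uses and that is placed on an alternative chromosome 6 sequence too, was also blank in both. HLA-DRA and TUBB are named here after their values were seen. Values of single HLA genes are uncertain because reads of similar HLA genes, and of the alternative chromosome 6 sequences in the gene table, can be split. Hypoxia and glycolysis genes had a median of -0.46 over 33 members (percentile 0.00), of which 2 were at least 2-fold lower, ENO2 (6.98 and 0.432 RPKM) and ALDOC (19.7 and 6.63 RPKM), and 1 higher, EGLN1.

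Cell-cycle and mitosis genes stood apart on the higher side by a small amount. Of 47 members 46 were positive, the median was 0.39 (percentile 100), and 2 reached 2-fold, CDK1 (4.81 and 14.6 RPKM) and NUF2 (12.4 and 30.2 RPKM). B-cell transcription factors had a median of 0.21 over 30 members (percentile 99.8), yet the farthest members were lower, IRF4 (73.9 and 14.6 RPKM), which drives plasma-cell differentiation, and RUNX3 (47.4 and 13.5 RPKM). Germinal-centre genes had a median of 0.24 over 28 members (percentile 99.8) and a mean of 0.04, with 0 members at least 2-fold higher and 2 lower. MEF2B (128 and 241 RPKM) stayed within 2-fold, and SERPINA9 was lower (22.2 and 0.067 RPKM). The list named chromatin silencing enzymes had a median of 0.26 over 27 members (percentile 99.8), none of them 2-fold different. It also lists genes that act against silencing, such as CREBBP, EP300 and TET2, so it is not a measure of silencing alone. Cytoplasmic ribosomal protein genes had a median of 0.15 over 47 members (percentile 99.8). Small and structural non-coding RNAs had a median of 0.31 over 8 members (percentile 97.9). They did not stand apart in 5 of the 11 alternatives in which the list was placed, at percentiles of 93.2 to 97.49. This list and that of ribosomal protein genes were fixed as measures of RNA quality. A difference in RNA selection or quality cannot be told apart from one in expression for them.

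Several programmes of interest in a treated lymphoma stayed within the range of random lists. B-cell receptor signalling genes had a median of -0.13 over 37 members, with 4 higher and 4 lower, among them BANK1 higher and RASGRP3 lower (15.1 and 3.13 RPKM). Death receptors, caspases and inhibitors of apoptosis had a median of -0.21 over 25 members (percentile 4.36), with 4 lower, among them TNFRSF1A (24.3 and 7.69 RPKM) and FAS (6.29 and 2.08 RPKM). Drug efflux transporters had a median of -0.08 over 6 members. The list of p53 targets had a median of -0.01 over 27 members, with 3 lower. MYC and ribosome-biogenesis genes (-0.06, 37 members), oxidative phosphorylation (-0.14, 38), proteasome subunits (-0.07, 31), cholesterol synthesis (0.06, 23), the unfolded protein and heat-shock response (-0.07, 30), histone genes (0.14, 13) and housekeeping genes (-0.07, 25) were also within it. Among 3 measured complement regulators, CD55 differed by -0.92, CD59 by -0.90 and CD46 by 0.26, and the median was that of CD59. Of the 18 immunoglobulin constant and surrogate light chain genes listed, only 4 were measured, with a median of -0.72. These were IGLL1, IGLL5, VPREB1 and VPREB3, so the median does not describe the immunoglobulin constant genes, which were not measured here. IGLL1 (24.6 and 2.05 RPKM) and IGLL5 (118 and 39.9 RPKM) are similar in sequence and can share reads.

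**Figure D3:**
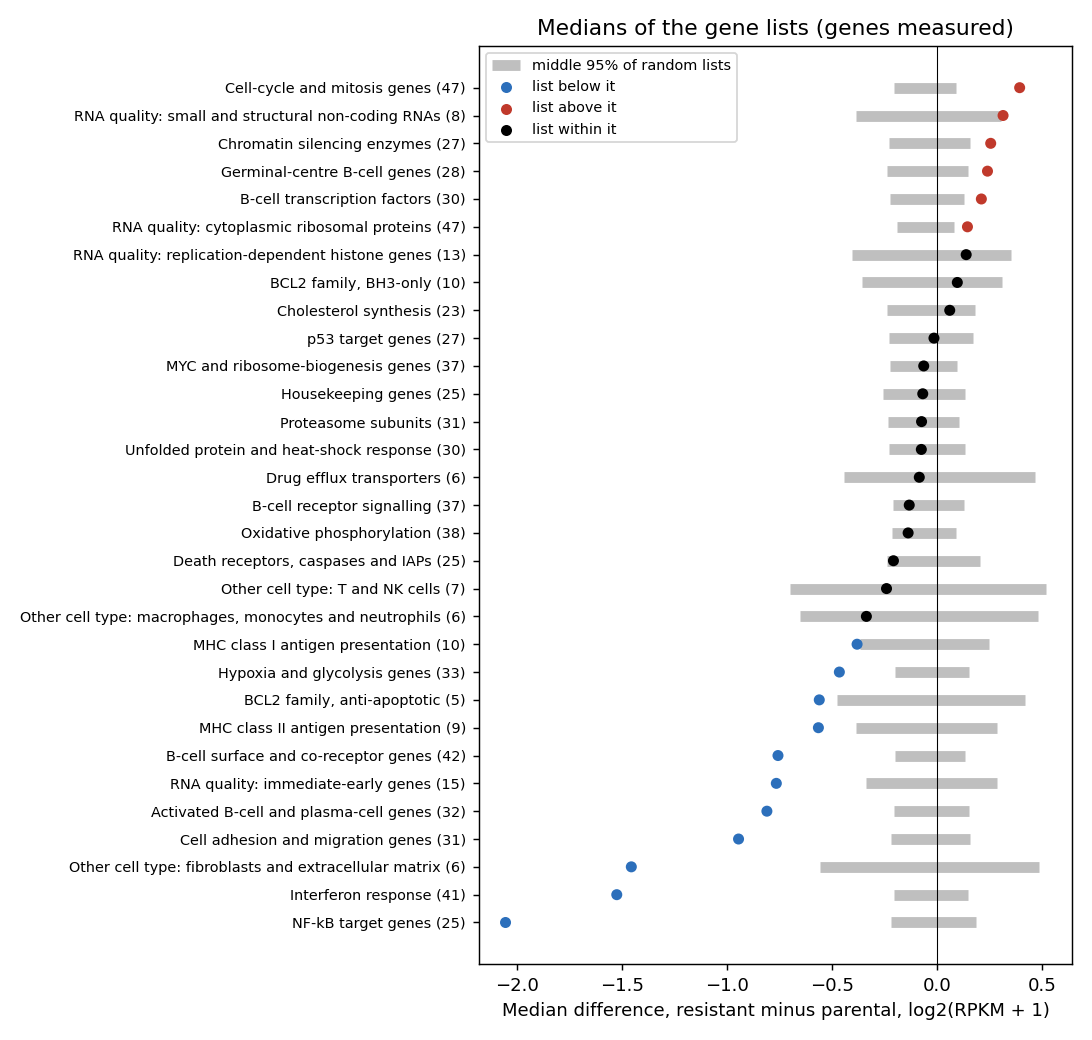
Median difference of log2(RPKM + 1), resistant minus parental, of each gene list with at least 5 members at the filter, with the number of members in brackets. Grey bars span the middle 95% of 10000 random lists, and NF-kB target genes (-2.05) and the interferon response (-1.52) lie farthest below theirs among the large lists.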

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

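GC-trend removal and leaving out haplotype sequences were chosen after the data were seen; the other 11 alternatives were fixed in advance. No replicate could be left out, since each group has 1 library. Of the values recomputed, 569 stayed within the set limits (0.58 on the log2 scale, or 1.5 times for a count), and 40 moved by more. These values were MS4A1, the BCL2 family genes, the list medians and the counts of higher and lower genes, so other called genes were not followed for sign. Of those among them called 2-fold different or standing apart 0 changed sign. By contrast, 17 uncalled values did, such as the myeloid and epidermis lists with a filter of 5 RPKM. The difference of MS4A1 and that of BCL2 stayed within the limits in the 7 alternatives in which they were recomputed, and 13 of 17 lists stood apart in every alternative in which they were placed. MHC class I and small non-coding RNAs did not. Nor did MHC class II and fibroblast markers without a filter, where members listed at 0 or near it hold the median near 0; the fibroblast list had too few members to be placed with a filter of 5 RPKM. Other scalings moved the median of all genes by under 0.1.

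The number of genes higher was 684 with a pseudocount of 0.1 RPKM, 93 with 5 RPKM, 728 with none, 258 with a filter of 5 RPKM, 46 at a 4-fold threshold and 1216 at 1.5-fold. The number lower was 272 with a pseudocount of 5 RPKM, 455 with the filter of 5 RPKM, 146 at 4-fold and 1645 at 1.5-fold. A larger pseudocount shrinks the differences of low genes, and the threshold sets the counts by construction. Removing the GC trend gave 435 higher and 627 lower genes, of which 352 and 599 were shared with the counts of the report. The fibroblast list had medians of -2.37 (pseudocount 0.1 RPKM), -0.63 (5 RPKM), -2.48 (none), -0.0021 (no filter) and -2.62 (filter 5 RPKM). With a pseudocount of 5 RPKM the interferon list was at -0.77 and the NF-kB list at -1.35, and without a filter the NF-kB list was at -0.82. With the filter of 5 RPKM the myeloid list was at 0.48 and the histone list at 1.66, over fewer genes. Depth limits genes near 1 RPKM, where counting error alone reaches 0.20 on the log2(RPKM + 1) scale for a 1 kb gene.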

Other observations

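All tests in this part, and the size of windows and limits they use, were chosen after the data were seen. Some of the genes that were lowest in the resistant library lay side by side in the genome. SLAMF1, CD48 and SLAMF7 are neighbours on chromosome 1 and differed by -3.91, -6.32 and -4.78, while the nearby CD84 (-0.74), SLAMF6 (-0.22) and F11R (-0.21), chosen after their values were seen, stayed within 2-fold on the log2(RPKM + 1) scale. CCL22 and CCL17 are close together on chromosome 16 and were the lowest pair, while CIAPIN1 and ARL2BP near them, chosen in the same way, differed by -0.17 and -0.50. Across the genome 84 pairs of neighbouring genes were both at least 2-fold lower, against a mean of 40.0 and a highest of 60 in 1000 shuffles of gene order. For both higher, the numbers were 38, 12.6 and 26, and outside the raised segments described below 26, 8.72 and 21. Neighbours that overlap can share reads, which can add to such pairs, and this was not tested. Within 2 Mb of MS4A1, 37 genes outside its family had a median of -0.17 and a lowest value of -3.39, and the neighbours TMEM132A (-2.68), SLC15A3 (-1.45) and CD6 (-1.67), chosen after their values were seen, were all at least 2-fold lower. Within 2 Mb of BCL2, 7 genes had a median of 0.06, but the highest 41 neighbouring genes on chromosome 18, a stretch that holds BCL2, had a median of 0.37. With the GC trend removed it was 0.32, against a highest of 0.35 in shuffles of values treated in the same way.

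Metallothionein genes on chromosome 16 did not differ as 1 block. MT2A (2.81), MT1F (3.32) and MT1X (2.66) were higher, while MT1G, MT1H and MT1E differed by 0.84, 0.70 and -0.30. Those other than MT2A and MT1F were chosen after their values were seen. MIR155HG, the host gene of a microRNA induced in activated B cells and chosen in the same way, was at 42.8 RPKM in the parental and 9.40 RPKM in the resistant library.

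Whole chromosome segments were higher in the resistant library, with medians of 0.45 over 263 genes on chromosome 12 (27.2 to 94.9 Mb, hg19), 0.62 over 63 genes on chromosome 13 (76.1 to 115.1 Mb) and 0.56 over 132 genes on chromosome 8 (74.7 to 142.4 Mb), against -0.02, 0.06 and -0.02 on the rest of each chromosome. GC content and scatter of single genes are argued against as the whole cause. The segments were joined from windows of 41 neighbouring genes whose median, GC trend removed, was at least 0.4 above that of all genes. Their lowest median of 0.44 with the trend removed follows from that choice and is no check on GC content. With the trend removed and as deposited, the highest windows were at 0.75 and 0.73 on chromosome 12 and 0.70 and 0.70 on chromosome 13. On chromosome 8 they were at 0.71 and 0.79. The highest window over 100 shuffles of gene order, with the trend removed, was at 0.35. On each of these chromosomes the highest window was also chosen with every other gene, 21 in all. The 20 genes left out inside it had medians of at least 0.61 with the GC trend removed. The chromosomes were chosen with all genes and these windows are only parts of the segments, so this does not check the segment medians. Extra copies in the resistant tumour, fewer copies in the parental tumour and regional control of expression cannot be told apart by these values. DNA was not analysed here.

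The NF-kB target and interferon lists were much lower in the resistant library. Scaling and GC content are argued against as the whole cause, since the higher of their 2 medians was -1.44 over 3 scalings and -1.48 with the GC trend removed. No gene of the list of macrophages, monocytes and neutrophils was higher in the parental library by more than 2.09 RPKM. The median excess over 65 members of the NF-kB target and interferon lists was 10.2 RPKM. Of the 26 myeloid genes, however, 9 were blank in both libraries and 20 were under the filter. How mouse reads were set apart is not given, so these values cannot decide whether host myeloid reads contribute. Cell types outside the myeloid list were not tested. A second human B-cell population in the parental tumour may also contribute: 11 genes were at 20 RPKM or more there and under 1 RPKM in the resistant library, against 0 the other way, and with 1 library per group this cannot be told apart from lower expression in the resistant cells.

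The cell-cycle list was higher by a small amount. Its median was 0.38 with the GC trend removed, at least 0.37 over 3 scalings and 0.39 without the member in the raised segments, so none of these accounts for all of it. A difference in the share of dividing cells may underlie it as a hypothesis, and tumour size or growth at collection is not given in the sources used here.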
